A study of Arachis hypogaea with 6 samples.

How the data were processed

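RNA was sequenced from the seed coat of peanut (Arachis hypogaea, an allotetraploid that carries an A and a B subgenome). The cultivar was J11, which the labels describe as resistant to invasion by the aflatoxin-producing mould Aspergillus flavus. Per the labels' protocols, field-grown plants were inoculated with conidia of isolate NRRL3357 at 25 days before harvest. Seed coats were collected 3, 5, 7 and 10 days later and pooled for RNA, so the infected libraries hold a mixture of times. The control libraries came from seed coats without infection, and their collection days are not stated in the labels. Each group had 3 libraries, which the series describes as biological replicates, and the labels ask for an RNA integrity number above 7.

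The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) per gene, a table of FPKM per transcript, and a transcript file for each library with coverage, FPKM and TPM. HISAT2 2.0.5 and StringTie 1.3.1 were used, per the submitters' processing notes. StringTie 1.3.1c quantified annotated transcripts only, against a joint annotation of Arachis duranensis (chromosomes A01 to A10) and Arachis ipaensis (chromosomes B01 to B10), per the file headers. These are the diploid relatives of the A and B subgenomes. The assembly versions, read filters and strand setting are not given in the sources used here, and coordinates are those of the deposited files. The transcript FPKM in the table and in each library's own file differed by at most 0. Control columns named C were matched to the libraries titled CK through the output folder in each file header. Infected columns and titles share the letter T, while the headers of those files name their output folders with E.

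The tables held 78064 genes and 105904 transcripts, with 36908 genes on A and 41156 on B chromosomes. Of the genes, 68966 had coding transcripts and 9098 had noncoding transcripts only. The files pair each numeric gene ID with the same number after LOC and give no gene name or product. Of these gene IDs, 0 were found in the reference gene table, which is from the assembly arahy.Tifrunner.gnm2.J5K5 of Arachis hypogaea, and 0 transcript accessions matched. The 38 planned gene lists (defence, phenylpropanoid, hormone, seed storage and others) were written as patterns on gene descriptions, so 0 of them could be joined and none gave a result. Markers of embryo, green or dividing cells could not be checked for the same reason. Genes are therefore described by position, structure and subgenome.

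Depth was taken from the ratio of coverage to FPKM within a library, which gives the aligned bases that StringTie divided by. The number of bases on transcripts with very little coverage was examined within a fixed range only. There the most frequent number was 291 to 296 per library. The median of these, 294, was taken as 1 fragment, from which fragment numbers were estimated. They are estimates, not counts. They cover counting error only, and PCR copies cannot be told from separate molecules. A value listed at 0 allows up to 3 fragments, which is 0.429 to 0.796 FPKM on a transcript of 1 kb, depending on the library.

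Genes with at least 1 FPKM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1). Changes are infected minus control on that scale, which understates the change of genes with low values. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Transcripts were tested the same way. The design was fixed before the data were examined, without the replicate number as a term. By the rule for naming genes, with no descriptions at most the 2 IDs with the largest rise and the 2 with the largest fall are printed. Other genes and regions are given by position and were chosen after their values were seen.

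Several analyses were added after the gene lists failed. The limma test camera, with a preset correlation of 0.01, compared each of 23 annotation sets with all other genes: the 20 chromosomes, noncoding genes, single-exon coding genes and coding genes of at least 10 exons. The limma test fry asked of each set whether its genes changed at all, on balance one way or in either direction. A-B gene pairs, here called homoeolog pairs, were built from gene structure: a coding transcript of at least 6 exons whose internal exons had the same lengths, in order, as those of exactly 1 gene of the other subgenome. Only pairs on same-numbered chromosomes were used. Genes with fewer exons, among them the 5 that passed the gene test, could not be paired. How reads that fit several places were handled is not given in the sources used here. The balance of a pair is the log2(FPKM + 1) of the A copy minus that of the B copy, tested with limma without a trend. Coverage along transcripts was summarised as the median log2 ratio of the mean coverage of the later exons to that of an equal number of earlier exons, over 1501 single-transcript coding genes with at least 5 exons, a length of 1500 nt and a coverage of 10 in each library. Values per library were compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1.

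Alternatives covered the pseudocount, the filter, scaling (quantile, median centring, TPM), the trend, limma's voom on coverage times length, the replicate number as a block, and each replicate left out. The scripts were tested on simulated data with spreads taken from these libraries, independent between genes. For the gene and transcript comparisons the spreads were partly smoothed over features of similar level. Their 4-fold and 8-fold changes were planted only at a mean of at least 5 FPKM, so recovery at lower levels was not tested. In the gene comparison (29352 genes), 91 of 100 genes changed 4-fold and 99 of 100 changed 8-fold were recovered, with 6 false calls. In the transcript comparison (31867 transcripts) the numbers were 72 and 95 of 100, with 11 false calls. For the pair balance (2480 pairs), 185 of 200 pairs shifted 4-fold were recovered with 9 false calls, and camera called the 1 shifted chromosome with 0 false calls. That chromosome's shift was larger than any chromosome difference reported below, so camera's recovery of shifts of those sizes was not tested. The libraries described here also share differences across many genes, which the simulation leaves out.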

Results

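Gene expression in the seed coat of the resistant peanut cultivar J11 was compared between plants inoculated with Aspergillus flavus and plants without infection, to describe expression early after infection. The data comprised 3 control and 3 infected libraries of the pooled seed coat. The control libraries held 1986.8, 1528.3 and 1595.6 megabases of aligned sequence, or about 6.76, 5.20 and 5.43 M fragments (M, mega). The infected libraries held 2054.0, 1163.8 and 1107.4 megabases, or about 6.99, 3.96 and 3.77 M fragments. Between 37091 and 41657 genes per library had a value above 0, and between 26941 and 29694 reached 1 FPKM. The infected group reached 1 FPKM for 27817 ± 1122 genes and the control group for 29070 ± 555 (SD, n = 3 each, exact permutation p = 0.3), with the lowest numbers in the 2 shallowest libraries, infected 2 and 3.

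The libraries did not group by infection along the main axis of variation. The first principal component, with 42.0% of the variance over the 29352 tested genes, placed control 1 (-67.5) beside infected 3 (-43.3) and infected 2 (-35.8). It placed control 2 (66.4), control 3 (56.8) and infected 1 (23.5) on the other side. Control 1 correlated with infected 2 and 3 at a mean r of 0.916 across genes and with the other controls at 0.867. Infected 1 correlated with controls 2 and 3 at 0.939 and with the other infected libraries at 0.934. The mean r was 0.892 within the control group, 0.935 within the infected group and 0.910 between them, across genes, which are not independent replicates. On the second component, with 22.6% of the variance, the infected libraries lay at 17.2 to 49.0 and the controls at -63.9 to 0.5. Coverage along transcripts, which can vary with RNA quality in a direction not established here, differed between the groups too. The later exons were covered less than the earlier ones in all 6 libraries, and the median log2 ratio was -0.65 ± 0.23 in the infected libraries (-0.61, -0.89 and -0.44) and -0.28 ± 0.13 in the controls (-0.24, -0.42 and -0.18; SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest this design allows).

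**Figure D1:**
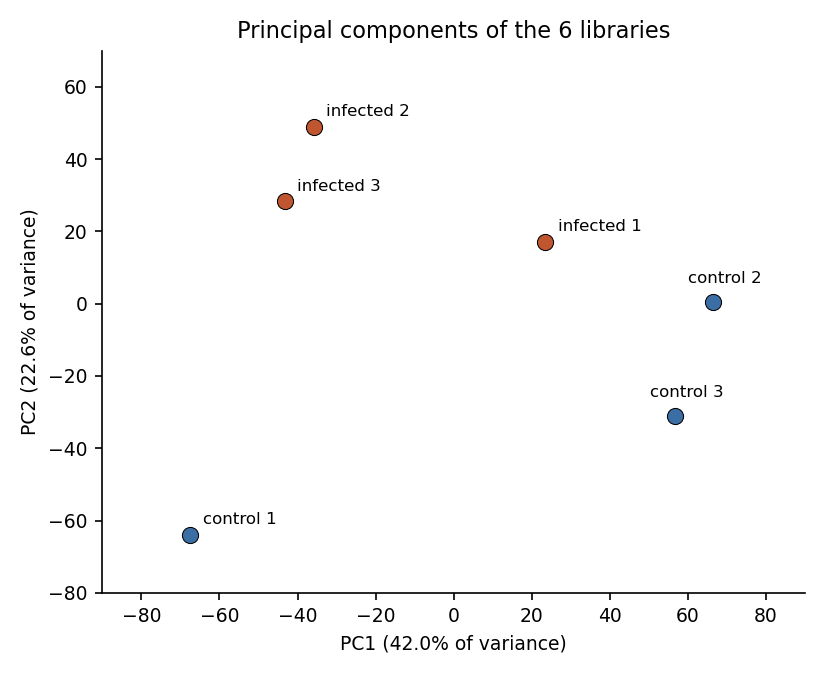
Position of each library on the first and second principal components of log2(FPKM + 1) over 29352 genes, in log2 units, with controls in blue and infected libraries in orange. Control 1 lies at -67.5 on the first component, on the side of infected 2 and 3, while infected 1 lies at 23.5, on the side of controls 2 and 3.

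Of the 29352 genes tested, 5 differed between infected and control seed coats, 2 higher and 3 lower in the infected libraries (limma, Benjamini-Hochberg adjusted p of 0.05). The most pronounced was a coding gene on chromosome A03 (LOC107481467, 125458255 to 125459150, plus strand, 2 exons, 868 nt). It stood at 190 ± 15.5 FPKM in the infected libraries against 0.880 ± 0.806 in the controls (SD, n = 3 each). Its log2 change was 6.75 ± 0.31 (SE), with a limma adjusted p of 0.000744. The infected values of 208, 180 and 182 FPKM rested on about 1260, 617 and 597 fragments, and the control values of 1.80, 0.282 and 0.561 FPKM on about 10.5, 1.3 and 2.6 fragments, so controls 2 and 3 lay under the level of 3 fragments and no fold is given. The 6 genes around it on A03, 3 on each side, were tested and did not pass, with log2 changes between -1.11 and 0.41.

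The other higher gene was a noncoding RNA gene on A06 (LOC107495206, 101615099 to 101616684, plus strand, 3 exons, 278 nt). It stood at 9.68, 8.97 and 9.76 FPKM in the infected libraries, about 18.8, 9.9 and 10.2 fragments, and was listed at 0 in the 3 controls, where 3 fragments would be 1.60 to 2.08 FPKM (log2 change 3.39 ± 0.21 SE, limma adjusted p = 0.00272). A noncoding RNA gene on B04 (LOC107635015, 119024172 to 119025857, plus strand, 3 exons, 533 nt) showed the reverse. It stood at 10.2, 10.8 and 8.98 FPKM in the controls and was listed at 0 in the infected libraries (log2 change -3.45 ± 0.22 SE, limma adjusted p = 0.00272).

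A single-exon coding gene on A10 (LOC107469805, 40974787 to 40975688, plus strand, 902 nt) had 22.3, 8.61 and 11.4 FPKM in the controls and was listed at 0 in the infected libraries (log2 change -3.81 ± 0.34 SE, limma adjusted p = 0.0240). Another annotated gene on the same strand, from 40974834 to 40975373, lies inside it. That nested gene averaged 49.2 FPKM in control and 26.6 FPKM in infected libraries and did not pass the test (adjusted p = 0.820), so the division of reads between them is uncertain. The remaining lower gene, named by position because it falls outside the naming rule, was a noncoding RNA gene on A09 (2369629 to 2370885, minus strand, 2 exons, 1174 nt). Its level was 8.90 ± 0.625 FPKM in controls and 0.504 ± 0.270 in infected libraries (SD, n = 3 each, limma adjusted p = 0.0227). Of the 5 genes, 4 lay on A chromosomes and 1 on a B chromosome, and 3 of the 5 were noncoding against 1701 of the 29352 tested. In each of the 5, the 3 infected libraries lay on one side of the 3 controls. The infected libraries were also those with the lower ratio of later to earlier exons. The A06, B04 and A10 genes had an SD of 0 in the group listed at 0. Their SE and p therefore rest on the spread of the other group and on spreads that limma shares between genes. Counting error in the group at 0 is not in them.

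**Figure D2:**
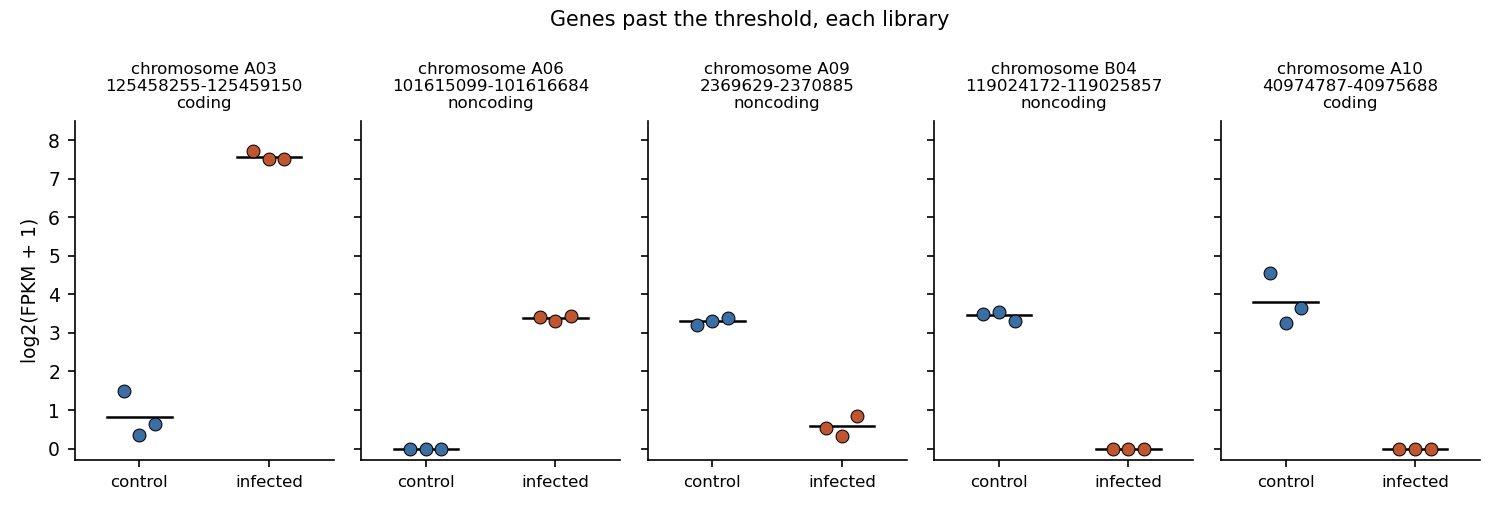
Expression of the 5 genes past the threshold as log2(FPKM + 1), with one point per library and a line at the group mean (3 libraries each). The A03 gene stands at 208, 180 and 182 FPKM in the infected libraries and between 0.282 and 1.80 FPKM in the controls.

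The number of changed genes rested on the settings and on single libraries: it was 1 with a filter of 5 FPKM or with voom, 3 with no filter, 44 (3 higher, 41 lower) without control 1, 3 without infected 2, and 1, the A03 gene, without infected 3. Without both control 1 and infected 1, a choice made after seeing the data, it was 345 (50 higher, 295 lower), and all 5 genes above were among these. The 5 had been called with these same libraries among others, so their return is no separate support. The excess of lower genes among the 44 and the 345 was not tested with median centring. Reads shared with near-identical copies elsewhere in the genome were not examined for any of the 5.

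At an unadjusted p under 0.05 stood 1875 genes (6.39% of those tested, the 5 included), of which 464 were higher and 1411 lower in infected libraries. The median change over all tested genes was -0.12 on the log2 scale. With each library centred on its median, which by itself brings both directions near balance, 824 were higher and 855 lower. The infected libraries lay wholly above the controls for 921 genes and wholly below for 2604, together 3525 genes or 12.01% of those tested, against 10% by chance. With centring these were 1697 and 1531 genes, together 3228. FPKM is scaled to the fragments of the library, so abundant genes that hold more of a library lower the values of the others. The abundant genes described next held more of each infected library. How far this accounts for the excess of lower genes was not tested.

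A few very abundant genes held a larger share of each infected library than of any control. The 3 genes with the highest mean FPKM over the 6 libraries were single-exon coding genes on B chromosomes: on B02 (105312996 to 105313662, 667 nt), on B04 (99332087 to 99332545, 459 nt) and on B06 (1474602 to 1474928, 327 nt). Together they held 19.6 ± 4.40% of the summed FPKM in infected and 9.74 ± 2.58% in control libraries (SD, n = 3 each). The infected libraries, at 17.7, 16.4 and 24.6%, lay above the controls at 6.76, 11.3 and 11.2% (exact two-sided permutation p = 0.1, the smallest this design allows). Ranked in the controls alone, the B06 gene gave way to a single-exon coding gene on A01 (36661995 to 36662781), and the 3 genes held 17.6 ± 2.88% in infected and 9.94 ± 1.74% in control libraries (SD, n = 3 each, exact permutation p = 0.1). The B02 gene stood at 68321 ± 14833 FPKM in infected and 35012 ± 10362 in control libraries, a 1.95-fold ratio, and the B04 gene at 66306 ± 22171 against 31258 ± 6423, a 2.12-fold ratio. The B06 gene stood at 23438 ± 17749 against 7740 ± 5133 and its groups overlapped. None of these 3 passed the gene test (limma adjusted p of 0.779, 0.762 and 0.790). The next most abundant, a single-exon coding gene on A03 (115622345 to 115623124), had a ratio of 1.94 and did not pass either (limma adjusted p = 0.762). Of the following 6 by mean FPKM, 4 had ratios of 0.775 to 0.997 and the others of 1.27 and 3.24, and none passed (limma adjusted p from 0.779 to 0.995). In each of the 6 the groups overlapped. Single libraries weighed on some ratios: control 2, at 13295 and 17751 FPKM, on those of 0.775 and 0.997, and infected 3, at 22331 FPKM, on that of 3.24.

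Genes on A chromosomes held a smaller part of the total in the infected libraries. Their share of summed FPKM was 39.2 ± 1.03% in infected and 42.9 ± 1.19% in control libraries (SD, n = 3 each), a difference of -3.70 percentage points, with each infected library below each control (exact two-sided permutation p = 0.1, the smallest possible). Without the 3 most abundant genes, a choice made after seeing the data, the share was 48.8 ± 1.55% in infected and 47.5 ± 0.077% in control libraries. The difference then turned to 1.27 points, with each infected library above each control (exact permutation p = 0.1), and was 0.379 points without infected 3. It was 0.376 points without the 100 most abundant genes and 0.19 points without the 3 genes most abundant in the controls (exact permutation p = 0.2).

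**Figure D3:**
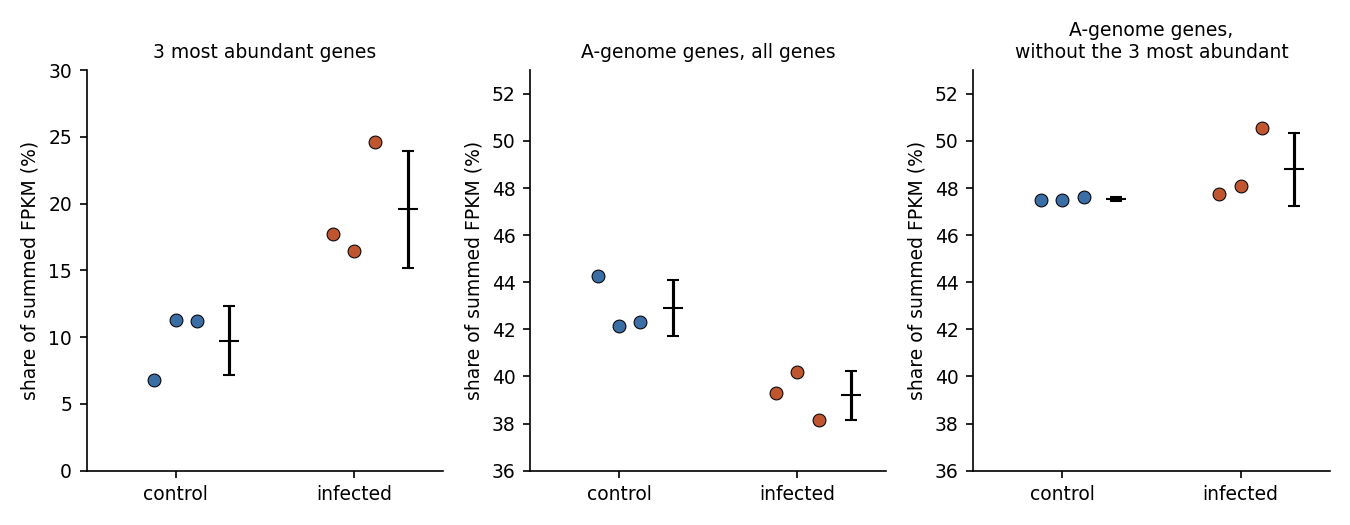
Share of summed FPKM, in percent, held by the 3 most abundant genes (left), by A-genome genes (middle) and by A-genome genes without those 3 (right), with one point per library and the mean ± SD beside it; the vertical axes of the A-genome plots start at 36%. The A-genome share is lower in infected libraries (39.2% against 42.9%) and is 48.8% against 47.5% once the 3 genes are left out.

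No chromosome or structural class passed the test against the other genes. Over the 20 chromosomes, the median log2 change relative to all tested genes ran from -0.026 on A09 to 0.019 on A07. It was 0.014 for the 1701 noncoding genes, 0.0011 for the 2957 single-exon coding genes and 0.018 for the 5979 coding genes of at least 10 exons. Of the 23 sets, 0 passed camera (lowest adjusted p = 0.977, and adjusted p = 0.986 with an estimated correlation), and 0 had an unadjusted p under 0.05 with camera. With fry, which tests a set against no change and not against other genes, 0 passed (lowest adjusted p = 0.144 in one direction and 0.284 in either direction).

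The balance between A and B copies did not pass the test for any pair, while the differences of the 2 copies correlated across pairs. Matching of exon lengths gave 4611 A-B gene pairs, of which 89.5% lay on same-numbered chromosomes against 10.6% after shuffling partners. Among the 2480 pairs with both copies tested, the B copy was the higher in 1576 and the A copy in 904. The B copy exceeded the A copy by at least 1 on the log2 scale in 265 pairs, and the reverse held in 104. The median balance was -0.17 ± 0.0025 in control and -0.17 ± 0.0090 in infected libraries (SD, n = 3 each, exact permutation p = 0.3). The balance of 0 pairs changed with infection (limma, lowest adjusted p = 0.0971), and 128 pairs (5.16%) had an unadjusted p under 0.05. The count was 1 without control 3, without infected 1 or without infected 3. The infected-minus-control differences of the copies correlated across pairs (Pearson r = 0.424, Spearman rho = 0.396), with both copies lower in 1257 pairs, both higher in 432 and opposite signs in 791, over a median change of -0.12 for all tested genes. After shuffling partners within deciles of the B copy's expression the median r was 0.005 and the highest of 10000 shuffles 0.097. Pairs are not independent replicates. Reads that fit both copies could make their differences move together, which was not examined and which shuffling partners does not remove. The same correlation over the other 9 divisions of the 6 libraries ran from 0.192 to 0.658.

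**Figure D4:**
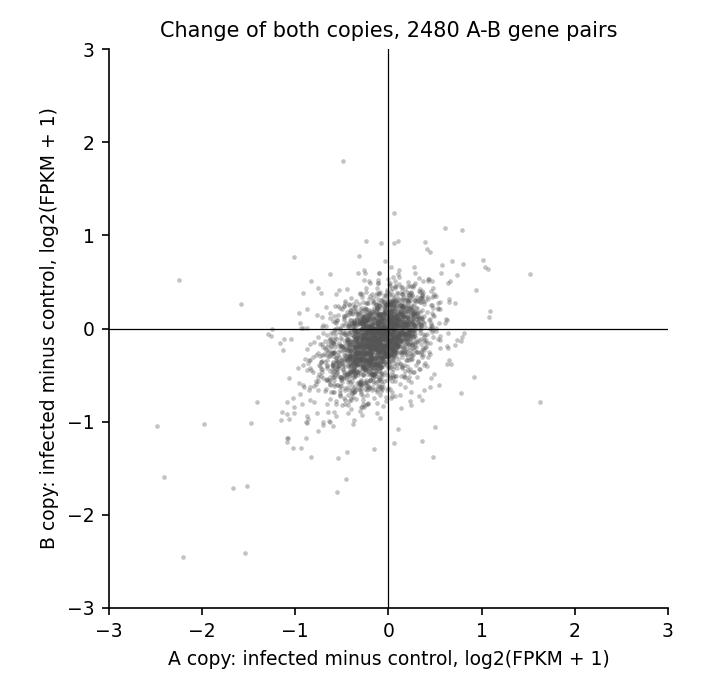
Difference of the A copy (horizontal) and of the B copy (vertical), infected minus control in log2(FPKM + 1), with one point for each of 2480 A-B gene pairs matched by exon lengths. The points run along the diagonal (r = 0.424), around a median of -0.12 for all tested genes.

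At the level of transcripts, 24 of 31867 tested passed the threshold, 11 higher and 13 lower in infected libraries. They belonged to 22 genes, and 5 were transcripts of the 5 genes above. The other 19 came from 17 genes that did not pass as a whole, each with more than 1 annotated transcript. Their median absolute log2 change was 2.97, against 0.286 for their genes, whose changes ran from -2.25 to 0.40, and 13 of the 24 were listed at 0 in all libraries of 1 group. In 2 genes, one transcript was higher and another lower. For the gene on A07 at 28482789 to 28484943, the transcript whose exon 2 had 444 nt stood at 9.35 ± 1.54 FPKM in controls and 0.324 ± 0.281 in infected libraries. The transcript whose exon 2 had 368 nt was listed at 0 in controls and stood at 8.56, 5.95 and 6.19 FPKM in the infected libraries. For the gene on B03 at 25014530 to 25023349, the transcript whose exon 4 had 90 nt stood at 9.71, 7.68 and 7.88 FPKM in controls and was listed at 0 in infected libraries, and the one whose exon 4 had 200 nt stood at 0.328 ± 0.283 and 7.69 ± 1.32 FPKM. The gene totals did not pass (log2 changes of -0.42 and -0.14, limma adjusted p of 0.820 and 0.934). The count of transcripts rested on the settings and on every library: it was 7 with a pseudocount of 0.1, 2 with no filter, 38 without control 1, 1 without control 2, 3 without control 3, 4 without infected 1, and 0 without infected 2 or without infected 3. The other 9 divisions of the 6 libraries mix infected and control libraries on each side. They gave 18, 16, 6, 29, 1, 2, 16, 6 and 64 transcripts past the threshold. Where all libraries of 1 group were listed at 0, that group added no spread to the test. Division of reads between transcripts can move with coverage along them, which differed between the groups.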

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

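The alternatives for annotation sets and pairs, the removal of the 3 most abundant genes (over all libraries or in controls) and the removal of control 1 and infected 1 together were chosen after seeing the data. The log2 changes of the 5 genes past the threshold kept their sign under each of 10 settings (pseudocount, quantile scaling, replicate block, each replicate left out, and control 1 and infected 1 left out together). This was nearly fixed in advance, since infected and control libraries did not overlap for any of the 5. The A03 gene LOC107481467 passed under all 10 (limma adjusted p from 4.30e-05 to 0.0277), LOC107495206 and LOC107635015 under 8 each, LOC107469805 under 5 and the A09 gene under 3. Not among the 10 were median centring, TPM, no trend and a minimum change of 1, where all 5 passed. Voom and a filter of 5 FPKM were not among them either, and there none of the 3 lower genes passed. With no filter, also outside the 10, 3 of the 5 passed. The count of 5 genes (2 higher, 3 lower) was the same with quantile scaling, median centring, TPM, no trend and a minimum change of 1, and was 4 with a pseudocount of 0.1. It was 3 (2 and 1) with no filter, and 1 (1 and 0) with a filter of 5 FPKM, with voom and with the replicate block. Leaving out 1 replicate gave 1 to 44 genes (1 to 3 higher, 0 to 41 lower; 44 without control 1, 3 without infected 2, 1 without infected 3), and leaving out control 1 and infected 1 together gave 345 (50 and 295). The count of 24 transcripts became 7 with a pseudocount of 0.1, 2 with no filter, 0 with the replicate block, 0 to 38 with 1 replicate left out and 13 without control 1 and infected 1. The annotation sets stayed at 0 under each setting, and the changed pairs at 0 except with 1 replicate left out, where they ranged from 0 to 1. The A-genome difference of -3.70 points was -3.68 with TPM and -4.20 to -3.02 with 1 replicate left out. Without control 1 and infected 1 together it was -3.06. It turned to 0.376 without the 100 most abundant genes, to 0.19 without the 3 most abundant in controls (2 on B, 1 on A chromosomes) and to 1.27 without the 3 most abundant over all libraries, which lie on B chromosomes. This last value was 0.379 to 1.80 with 1 replicate left out, the lowest without infected 3. The replicate numbers did not pair the samples: deviations from the group means correlated at -0.421, -0.070 and -0.157 for numbers 1, 2 and 3. The fixed gene lists gave no value under any setting, because no description could be joined. Depth limits what a value of 0 shows, since 3 fragments on a transcript of 1 kb are 0.758 and 0.796 FPKM in infected 2 and 3. For the changes with the pseudocount, filter, voom and replicate block, the cause was not tested.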

Other observations

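The tests of gene counts over the splits, of exon coverage and of the shift in median pair balance were chosen only after the result was seen, as were the removal of the 3 most abundant genes and of control 1 and infected 1 together, while the annotation sets and pairs were added after the planned gene lists failed. The exon-length pairs also joined differently numbered chromosomes: 182 pairs joined A08 with B07 and 86 joined A07 with B08, while no other such combination held more than 23. The B copy was above the A copy in all 6 libraries for 786 of the 2480 tested pairs, and the A copy above the B copy in all 6 for 328.

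The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For changed genes, 2 of the 10 splits, the real one with 5 included, gave at least as many, and the highest other gave 337. For transcripts, 3 of the 10, the real one with 24 included, gave at least as many, and the highest other gave 64. The real split called 0 annotation sets and 0 changed pairs, so 10 of 10, itself included, gave at least as many, with a highest other of 2 in both cases. The lowest adjusted p of any gene, 0.000744, came from the real split.

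The split with 337 genes put control 1, infected 2 and infected 3 against control 2, control 3 and infected 1, which points to a structure of the libraries other than the labelled infection. Unequal depth as the whole cause is argued against, since the split still called 270 genes after all libraries were thinned to the shallowest. RNA fragmentation stays open. The coverage ratios of the 3 libraries interleaved with those of the others, and their mean difference of -0.118 lay within the pooled SD of 0.280. The test took a lower ratio of later to earlier exons as the mark of fragmentation, a direction that was assumed and not established here. An exchange of the labels of control 1 and infected 1 cannot be told apart from another difference between the plants or pools: of 345 genes called between the other 4 libraries, 82.9% had control 1 nearer to the infected mean but only 59.7% had infected 1 nearer to the control mean. Against an exchange stand the top-3 and A-genome shares, which separate by the given labels. These measures are not independent, since the same abundant genes enter both. Each reached only the smallest possible exact permutation p of 0.1. The count of changed genes goes the other way: the exchanged labels are the split with 337 genes, against 5 with the labels as given. The lowest adjusted p was 0.000744 with the labels as given and 0.0157 with them exchanged (limma). The first belongs to the A03 gene, among the 5 past the threshold, which separate by the given labels but were chosen by them. No biological explanation was tested, since the design names only infection, and whether the 345 genes follow infection stays open.

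The lower A-genome share of the infected libraries is consistent with a few abundant B-genome genes taking more of a fixed total. Without the 3 most abundant genes the difference became 1.27 percentage points in the other direction (0.379 without infected 3), and without the 3 most abundant in controls, a choice that the infected level does not enter, it was 0.19. Among the pairs, a general shift from A to B copies is argued against. The observed shares would need a move of about -0.22 on the log2 scale, while the median balance of the pairs moved by -0.0073, with an SD of 0.0071 over the 6 libraries. The pairs hold only coding genes of at least 6 exons and count alike, whereas the shares weigh all genes by abundance. Genes outside the pairs, and reads that fit both copies, were not examined in this way. What those single-exon genes encode, and whether infection or another difference between the groups goes with their level, stays open.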
